A study of Homo sapiens with 15 samples.

How the data were processed

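The series holds 15 arrays of C42B cells in 6 groups. Per the labels' protocols, 140000 cells per well were grown in 2 ml of medium with 10% serum for 3 days, treated for 6 h, and 100 ng of total RNA was labelled for a whole-transcript Affymetrix array. Vehicle was 0.125% DMSO for the DMSO arrays, and no DMSO percentage is recorded for the treated arrays. The group of each array came from its labels. The single ABC294640 array carries no replicate number in its label.

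The deposited values are log2 expression per probe set, with RMA and Transcriptome Analysis Console 4.02 as the authors' tools per the submitters' processing notes. RMA corrects for background, normalizes between arrays and summarises probes per probe set. The RMA variant and the annotation version are not given in the sources used here. Column medians lay between 6.71 and 6.76 on all 15 arrays. The SD over probe sets was 3.2949 to 3.3143 on the DMSO arrays and 3.3241 to 3.3643 on the others. The values were used without further normalization, with other normalizations as alternatives. RMA brings arrays towards a common distribution, so a change shared by most genes would not be seen. Scanner files and detection calls were not used here, so no probe set was judged against background.

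Of 21448 probe sets, 17709 had 1 gene symbol in the platform annotation, 0 had several and 3739 were unnamed here. All 17709 matched a RefSeq gene through their Entrez identifier, and 0 symbols changed. For the 20 genes with several probe sets, the one with the highest mean over all arrays was kept, which left 17687 genes. SPHK2 was to be named in any case and is not analysed here. Some genes that the rule for named genes picks are not reported here. Coordinates are not printed, since the build behind the probe sets is not given in the sources used here.

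Gene tests used limma 3.58.1 in R 4.3.3. A mean per group was fitted to all 15 arrays (9 residual degrees of freedom, 3.82 prior degrees of freedom), with empirical Bayes moderation, 12 contrasts and Benjamini-Hochberg adjustment over all genes within a contrast, at a threshold of 0.05. A log2 difference is given with its standard error, and 95% intervals used the moderated degrees of freedom. The pooled fit lends the single ABC294640 array the spread of the other groups.

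The 31 gene lists were fixed before the data were examined, with 617 members of which 543 were measured. Each list was tested with camera at a preset inter-gene correlation of 0.01, with the correlation estimated from the data, and with fry, which asks whether a list's genes move one way and does not compare them with other genes. List p-values were adjusted over the 31 lists within a contrast. Single members were adjusted over all genes and also over the list alone.

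Also fixed before the data were examined were the contrasts, the alternatives and the rule for named genes. The rule took the 10 largest rises and the 10 largest falls past the threshold, with no overlap between the 2 groups' arrays, for each single agent against DMSO and each combination against enzalutamide, and the 5 largest of each for the other contrasts. Where no gene passed, the 3 with the smallest p are given as values. The up to 4 members with the largest change of each list past camera, and SPHK1, were added. STC2, PSPH and SESN3, the genes whose effects are followed from one comparison into another, and the 12 plotted genes were chosen after their values were seen.

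Alternatives fixed in advance were quantile normalization, centring of array medians, leaving out the dimmest 25% of genes, testing all probe sets, a robust and trended prior, array weights, fitting only the arrays of a contrast, the replicate number as a block, a minimum of 2-fold with adjusted or unadjusted p, and leaving out each array in turn. After the DMSO arrays were seen to stand apart, cyclic loess normalization and contrasts without DMSO arrays were added. No label gives a date or batch. The number of identical pairs of arrays was 0. The columns of all arrays were used.

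The gene test was checked on simulated data with 200 changed genes of 17687. For PF-543 against DMSO it recovered 24% of genes changed by log2 0.5 and 96% of those changed by 1, with 10 false calls. For enzalutamide against DMSO it recovered 12% and 86%, with 9 false calls, and for the combination with PF-543 against enzalutamide 28% and 82%, with 5 false calls. In the simulation each gene had the same spread in every group, genes varied independently, and the DMSO arrays were not shifted. Recovery and false calls in the real data may therefore differ. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.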

Results

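Gene expression was measured on 15 whole-transcript Affymetrix arrays, each hybridised with RNA from C42B cells, a castration-resistant human prostate cancer line of the LNCaP lineage. The cells were exposed for 6 h to the vehicle dimethyl sulfoxide (DMSO, 3 arrays), to 10 µM enzalutamide (2 arrays), to 15 µM PF-543 (3 arrays) or to 15 µM ABC294640 (1 array). Enzalutamide was also combined with PF-543 (3 arrays) and with ABC294640 (3 arrays) at the same doses. Enzalutamide is a drug that blocks the response to androgen, PF-543 an inhibitor of sphingosine kinase 1, and ABC294640 (opaganib) an inhibitor of sphingosine kinase 2. The labels do not say whether replicates were separate cultures, so p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision, and the single ABC294640 array was assumed to vary like the arrays of the other groups.

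The 3 DMSO arrays stood apart from all 12 arrays of treated cells. On the first principal component, which held 15.3% of the variance over 17687 genes, the DMSO arrays lay between 18.9 and 24.8, and the treated arrays between -11.6 and 0. The mean correlation of a DMSO array with a treated array was 0.9946, against 0.9956 between treated arrays of different groups. It was 0.9954 among the DMSO arrays and 0.9960 between treated arrays of the same group. For this reason each single drug's comparison with DMSO is given together with a comparison of the same drug that used no DMSO array. Only the log2 differences of such comparisons are free of the DMSO arrays. Their p-values rest on the spread pooled over all 15 arrays. The comparisons of the combinations with DMSO have no such counterpart, since no other group lacked both drugs.

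**Figure D1:**
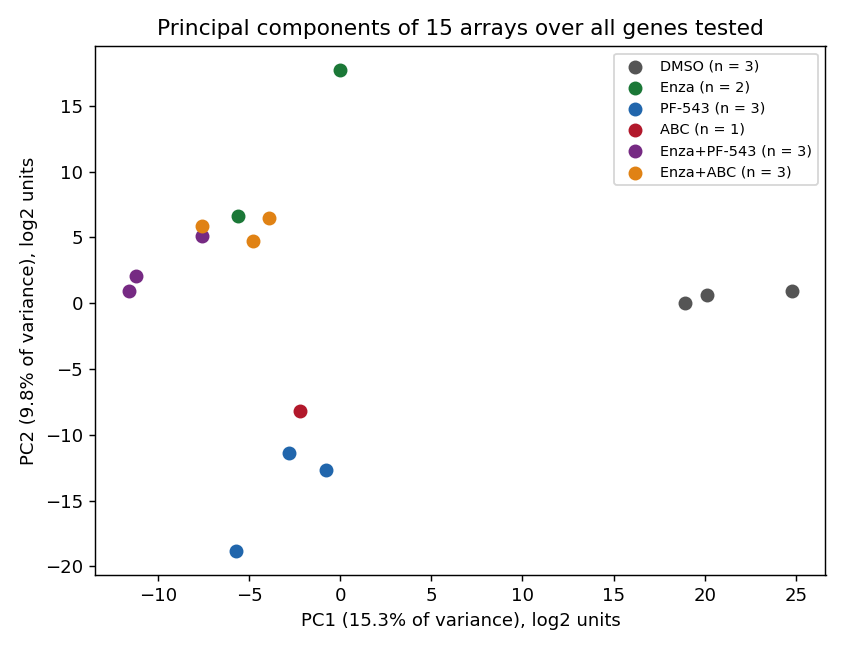
Scores of the 15 arrays on the first (15.3% of variance) and second (9.8%) principal components over all genes tested, in log2 units, 1 point per array and 1 colour per group. The 3 DMSO arrays lie at 18.9 to 24.8 on the first component, and every treated array lies at or below 0.

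The effect of blocking the androgen response was read from enzalutamide against DMSO. Genes induced by androgen fell. C1orf116, an androgen-regulated gene, went from 12.71 ± 0.11 (SD, n = 3) in DMSO to 10.16 ± 0.08 (SD, n = 2) in log2 units, a 5.86-fold decrease (log2 -2.55, SE 0.12, limma adjusted p = 3.6e-07). ZBTB16, a transcription factor, was 4.99-fold lower (log2 -2.32, SE 0.18, adjusted p = 4.71e-05) and PMEPA1, an androgen-induced membrane protein that restrains TGF-beta signalling, was 2.6-fold lower (log2 -1.38, SE 0.17, adjusted p = 0.00321). Of 29 measured androgen-induced genes, 8 fell, 0 rose and 21 did not pass; 15 fell when p was adjusted over the list alone. The list shifted down as a whole (median log2 -0.38, camera adjusted p = 2.96e-17; adjusted p = 0.00166 with an estimated correlation).

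Outside that list, enzalutamide lowered the transcription factors SNAI2 (log2 -1.99, SE 0.34) and KLF5 (log2 -1.55, SE 0.19) and the Cdc42 effector CDC42EP3 (log2 -1.96, SE 0.20), with limma adjusted p from 0.000604 to 0.0267. The kinase MAK and the NADPH oxidase subunit CYBB, at log2 -1.20 and -1.16, were also among the 10 largest falls, as was MAF of the androgen-induced list (log2 -1.24). The glucocorticoid receptor list, which shares ZBTB16 with the androgen list, shifted down with 2 of 10 members lower, ZBTB16 and the EGFR inhibitor ERRFI1 (camera adjusted p = 0.00017, and adjusted p = 0.0618 with an estimated correlation). When p was adjusted over the list alone, 3 members fell and 1 rose, and TSC22D3 of this list was at log2 0.48. Of 20 cholesterol genes none passed singly, while the list's median lay at log2 -0.19 (camera adjusted p = 0.00619; adjusted p = 0.0795 with an estimated correlation).

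Targets of ATF4, the transcription factor of the integrated stress response, rose with enzalutamide. DDIT4, an inhibitor of mTORC1 signalling, was 2.28-fold higher (log2 1.19, SE 0.14, limma adjusted p = 0.00284), and CHAC1, which degrades glutathione, was also 2.28-fold higher (log2 1.19, SE 0.12, adjusted p = 0.000604). Of 33 measured members 5 rose (DDIT4, CHAC1, SESN2, SLC6A9 and STC2), 0 fell and 28 did not pass; 12 rose when p was adjusted over the list alone. The whole list shifted up (median log2 0.22, camera adjusted p = 4.94e-10; adjusted p = 0.00402 with an estimated correlation). The MYC and ribosome biogenesis list also shifted up, with 1 of 18 members higher, MYC itself (log2 0.58, SE 0.09, adjusted p = 0.0134; camera adjusted p = 5.5e-05, and adjusted p = 0.0427 with an estimated correlation). A further 4 lists passed camera with no member passing singly over all genes, and each lost the call with an estimated correlation. They were the metallothioneins (median log2 0.26, adjusted p = 0.000126, then adjusted p = 0.149), heat shock genes (0.10, adjusted p = 0.00619, then adjusted p = 0.243), ribosomal proteins (0.09, adjusted p = 0.0114, then adjusted p = 0.3) and fatty acid synthesis genes (0.12, adjusted p = 0.0484, then adjusted p = 0.258).

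In all, 22 genes were higher and 33 lower with enzalutamide than with DMSO (limma, adjusted p under 0.05; 2273 genes had an unadjusted p under 0.05, where 884 would by chance). The count was 32 without DMSO replicate 2, 19 without enzalutamide replicate 1 and 12 without enzalutamide replicate 2. The mean enzalutamide effect in cells that also received an inhibitor, which uses no DMSO array, called 68 genes, 32 of them among the 55. In that comparison C1orf116 (log2 -2.45), ZBTB16 (-2.14), PMEPA1 (-1.59), DDIT4 (1.18) and CHAC1 (1.37) again passed. Several of the 10 largest rises against DMSO did not: MRGPRD was at log2 0.17 instead of 1.39, MAP3K8 at 0.19 instead of 1.28, FAM114A1 at 0.05 instead of 0.90, BOK at 0.08 instead of 0.79, DCAF4 at 0.14 instead of 0.76, and TLK1 at -0.17 instead of 0.89. SESN2 was at 0.61 (adjusted p = 0.078), MYC at 0.20 (adjusted p = 0.422) and CYBB, which fell against DMSO, at 0.24. SNAI2 (log2 -2.31), CDC42EP3 (-1.91), KLF5 (-1.79) and MAF (-1.76) passed, and MAK (-0.75 instead of -1.20), ERRFI1 (-0.53 instead of -0.93) and SLC6A9 (0.50 instead of 0.88) passed with smaller differences. This mean gives the single ABC294640 array as much weight as the 3 PF-543 arrays. With PF-543, adding enzalutamide took mean MRGPRD from 5.38 to 5.83, MAP3K8 from 7.57 to 8, BOK from 7.45 to 7.73 and DCAF4 from 9.73 to 9.97. FAM114A1 went from 6.7 to 6.63 there, TLK1 from 10.84 to 10.9 and CYBB from 5.06 to 5.05. With ABC294640, TLK1 went from 11.15 to 10.75 and CYBB from 4.41 to 4.89.

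The lists called for enzalutamide against DMSO were also computed without the DMSO arrays, as means over members. Androgen-induced genes were at log2 -0.59 (camera adjusted p = 1.14e-34), ATF4 targets at 0.35 (adjusted p = 1.81e-23), cholesterol genes at -0.19 (adjusted p = 3.73e-07), glucocorticoid receptor targets at -0.32 (adjusted p = 0.000675) and metallothioneins at 0.16 (adjusted p = 0.00802). With an estimated correlation the last 2 lists passed neither on top of PF-543 (adjusted p = 0.112 and 0.783) nor on top of the single ABC294640 array (adjusted p = 0.328 and 0.402). The metallothionein mean was 0.06 on top of PF-543 (camera adjusted p = 0.513) and 0.25 on top of that array, and cholesterol genes were at -0.27 and -0.11 (camera adjusted p = 1.9e-09 and 0.0907). The other called lists did not pass without DMSO. MYC and ribosome biogenesis genes were at 0.07 (adjusted p = 0.143), and heat shock, fatty acid synthesis and ribosomal protein genes, which were above 0 against DMSO, were at -0.005, -0.08 and -0.004.

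The response to 15 µM PF-543 was read from its comparison with DMSO, and the activity of sphingosine kinase 1 was not measured on these arrays. Genes of cholesterol synthesis and uptake rose. HMGCS1, which makes HMG-CoA for the mevalonate pathway, went from 11.33 ± 0.23 (SD, n = 3) to 12.79 ± 0.12 (SD, n = 3), a 2.75-fold increase (log2 1.46, SE 0.13, limma adjusted p = 0.000236). INSIG1, which holds the SREBP escort protein in the endoplasmic reticulum, was 2.66-fold higher (log2 1.41, SE 0.12, adjusted p = 0.000228), and the sterol enzyme MSMO1 was 2.15-fold higher (log2 1.11, SE 0.09, adjusted p = 0.000228). Of 20 measured members 8 rose, 0 fell and 12 did not pass; 13 rose when p was adjusted over the list alone (median log2 0.52, camera adjusted p = 3.1e-17; adjusted p = 0.000396 with an estimated correlation).

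Fatty acid synthesis genes rose as well with PF-543, with 5 of 12 members higher and 0 lower, and 8 higher when adjusted over the list alone (median log2 0.32, camera adjusted p = 3.5e-11; adjusted p = 0.00669 with an estimated correlation). ACSS2, which makes acetyl-CoA from acetate, was 2.79-fold higher (log2 1.48, SE 0.18, limma adjusted p = 0.00231), the elongase ELOVL6 1.89-fold (log2 0.92, SE 0.10, adjusted p = 0.000705) and the fatty acid synthase FASN 1.67-fold (log2 0.74, SE 0.10, adjusted p = 0.00648). Of the ATF4 list 3 of 33 members rose, DDIT4 (log2 1.09, SE 0.13), CHAC1 (log2 0.69, SE 0.11) and PSPH (camera adjusted p = 4.07e-05; adjusted p = 0.0307 with an estimated correlation). NRF2 targets shifted up by camera with 1 of 23 members higher, ME1, which also stands in the fatty acid list (adjusted p = 0.0092; adjusted p = 0.127 with an estimated correlation). Immediate early genes shifted up with none of 22 passing singly (adjusted p = 0.014; adjusted p = 0.0652 with an estimated correlation). The other large rises were the lipase LIPG (log2 1.10), the ubiquitin ligase TRIM2 (1.05), IDI1 of the mevalonate pathway (1.05), the protein kinase C isoform PRKCH (1.05) and PCYT2 of phosphatidylethanolamine synthesis (0.99).

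In all, 64 genes were higher and 36 lower with PF-543 than with DMSO, and leaving out any 1 of the 6 arrays gave 25 to 59 genes in place of 100. The 10 largest falls, among them USP26 (log2 -1.26, SE 0.22), LRRC74A (-1.18, SE 0.16) and ANKS1B (-1.09, SE 0.19), belonged to none of the lists. Some were dim, with USP26 going from a mean of 5.32 to 4.07 and LRRC74A from 5.83 to 4.65. The first quartile of signal was 4.65 to 4.69 on the DMSO arrays and 4.57 to 4.63 on the treated ones. ANKS1B went from 6.42 to 5.32, and CASP16P (9.68 to 8.54) and ZFTA (14.26 to 13.26) were brighter. Enzalutamide alone also had lower means than DMSO for USP26 (4.31), LRRC74A (5.52), ANKS1B (5.42), CASP16P (9) and ZFTA (13.78). On the single ABC294640 array they were at 3.39, 4.81, 5.3, 9.03 and 14.01. The DMSO arrays that picked these genes enter all of these differences. Against enzalutamide alone, where no DMSO array enters, the combination with PF-543 had 23 of these 36 genes at the same sign, with a median of log2 -0.05 against -0.76. The 64 rises had 55 genes at the same sign, with a median of 0.32 against 0.67. HMGCS1 was there at log2 0.68, ACSS2 at 0.85, LIPG at 0.59, TRIM2 at 0.40, PRKCH at 0.39 and PCYT2 at 0.25, none of them past the threshold. ELOVL6 (log2 0.68, adjusted p = 0.0565), FASN (0.61, adjusted p = 0.14), ME1 (0.21, adjusted p = 0.716), CHAC1 (0.79, adjusted p = 0.055) and PSPH (0.38, adjusted p = 0.413) did not pass there either, while INSIG1, MSMO1, IDI1 and DDIT4 passed. USP26, LRRC74A and ANKS1B were there at log2 -0.31, -0.32 and 0.14, none past the threshold. Immediate early genes were at a mean of log2 0.04, against 0.14 with DMSO as the reference (camera adjusted p = 0.944). SPHK1, the gene of the kinase that PF-543 inhibits, was at log2 -0.57 (SE 0.12, limma adjusted p = 0.0636), and at -0.24 without the DMSO arrays (adjusted p = 0.725).

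**Figure D2:**
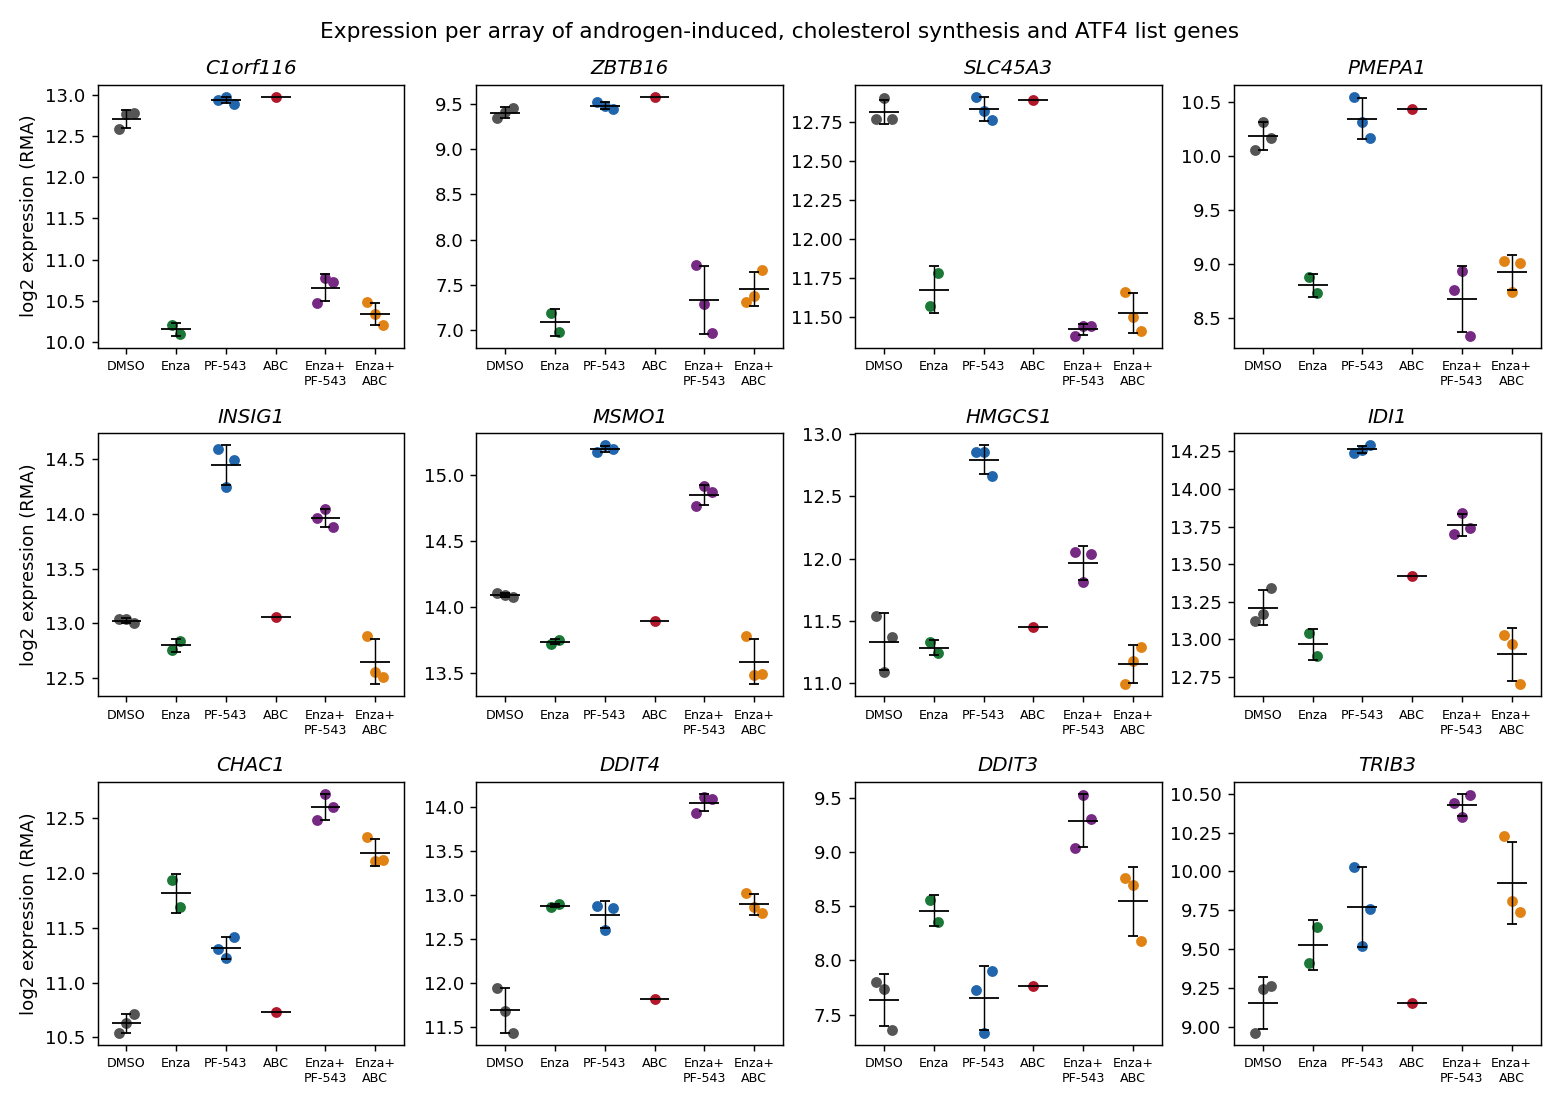
Log2 expression of 12 genes on each of the 15 arrays, by group, with points for arrays, a horizontal line for the group mean and bars for the SD (no bar for the single ABC294640 array). C1orf116 is lower in the 3 groups with enzalutamide, INSIG1 is higher in the 2 groups with PF-543, and DDIT4 is highest with enzalutamide plus PF-543 at 14.04 ± 0.10.

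ABC294640 against DMSO rested on 1 treated array. No gene passed (limma, smallest adjusted p = 0.14; 1693 genes had an unadjusted p under 0.05, where 884 would by chance; 8 passed with a robust prior trend), and none of the 31 lists passed camera, camera with an estimated correlation or fry. The genes with the smallest p were RYR1 (log2 -1.10, SE 0.16), TKTL1 (-0.93, SE 0.15) and BMP6 (1.14, SE 0.18), all at adjusted p = 0.136. On top of enzalutamide, without DMSO arrays, RYR1 was at log2 0.03, TKTL1 at -0.15 and BMP6 at -0.10. The cholesterol gene INSIG1 was at log2 0.03 (95% CI -0.32 to 0.39) and C1orf116 at 0.26 (95% CI -0.06 to 0.59). In simulated data, where the single array was given the same spread as the others, this comparison recovered 74% of genes changed by log2 1 and 6% of those changed by 0.5. SPHK1 was at log2 -0.58 (SE 0.17, adjusted p = 0.33), and at -0.27 on top of enzalutamide (adjusted p = 0.765). Without DMSO replicate 1 the count was 1 gene.

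Whether PF-543 added to enzalutamide was read from the combination against enzalutamide alone. With PF-543 added, 5 genes were higher and 0 lower. DDIT4 rose 2.25-fold (log2 1.17, SE 0.14, limma adjusted p = 0.0118), INSIG1 2.23-fold (log2 1.16, SE 0.13, adjusted p = 0.00656), MSMO1 2.16-fold (log2 1.11, SE 0.10, adjusted p = 0.0016), the stress-induced transcription factor ATF3 2.07-fold (log2 1.05, SE 0.15, adjusted p = 0.0305) and IDI1 1.74-fold (log2 0.80, SE 0.12, adjusted p = 0.0413). INSIG1, MSMO1 and IDI1 were the 3 of 20 cholesterol genes that passed, and 12 passed when adjusted over the list alone (median log2 0.39, camera adjusted p = 5.92e-18; adjusted p = 0.000335 with an estimated correlation). Of the ATF4 list 2 of 33 rose, DDIT4 and ATF3, and 12 when adjusted over the list alone (median log2 0.18, camera adjusted p = 9.57e-12; adjusted p = 0.00221 with an estimated correlation).

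Another 3 lists passed camera in this comparison with no member passing singly, and lost the call with an estimated correlation. Fatty acid synthesis genes had a median of log2 0.21 (adjusted p = 0.000104, then adjusted p = 0.0816), NRF2 targets 0.07 (adjusted p = 0.0397, then adjusted p = 0.279) and MYC and ribosome biogenesis genes -0.07 (adjusted p = 0.023, then adjusted p = 0.267). The androgen-induced list did not pass, and C1orf116 differed by log2 0.51 (95% CI 0.25 to 0.76, limma adjusted p = 0.286). Leaving out 1 array lowered the 5 genes to between 0 and 3, with 0 without either enzalutamide array, and the fit on these 5 arrays alone gave 0. The 5 lists became 3 without enzalutamide replicate 2 or without replicate 2 of the combination.

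ABC294640 added to enzalutamide gave no gene past the threshold against enzalutamide alone (limma, smallest adjusted p = 0.46; 1200 genes with an unadjusted p under 0.05 and 884 by chance; 1 gene with a robust prior trend). The smallest p belonged to CST4 (log2 -0.72, SE 0.12), ZBTB14 (0.57, SE 0.10) and TAFA3 (-0.80, SE 0.15), each at adjusted p = 0.459. Heat shock genes were the 1 list past camera, with none of 16 members passing singly (median log2 -0.11, adjusted p = 0.00249; adjusted p = 0.84 with an estimated correlation), and the list was not called without enzalutamide replicate 2 or without replicate 1 of the combination. INSIG1 differed by log2 -0.15 (95% CI -0.43 to 0.14) and DDIT4 by 0.02 (95% CI -0.30 to 0.33).

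The combinations were compared directly, at 15 µM of either inhibitor with 10 µM enzalutamide. With PF-543 in place of ABC294640, 16 genes were higher and 1, the glucose transporter family gene SLC2A7, was lower (log2 -0.54, SE 0.09, limma adjusted p = 0.0358). INSIG1 was 2.47-fold higher (log2 1.31, SE 0.12, adjusted p = 0.000467), MSMO1 2.4-fold (log2 1.26, SE 0.09, adjusted p = 9.36e-05), DDIT4 2.22-fold (log2 1.15, SE 0.13, adjusted p = 0.00396), ACSS2 2.15-fold (log2 1.10, SE 0.18, adjusted p = 0.0358) and the stress cytokine GDF15 2.07-fold (log2 1.05, SE 0.17, adjusted p = 0.0377). Of 20 cholesterol genes 5 were higher and 0 lower, and 11 were higher when adjusted over the list alone (median log2 0.43, camera adjusted p = 2.27e-22; adjusted p = 0.000135 with an estimated correlation). Fatty acid synthesis genes (2 of 12 higher, camera adjusted p = 9.57e-10; adjusted p = 0.00777 with an estimated correlation) and ATF4 targets (3 of 33 higher, camera adjusted p = 1.82e-11; adjusted p = 0.00243 with an estimated correlation) were also higher. MYC and ribosome biogenesis genes were lower by camera, with none of 18 passing singly (adjusted p = 0.0284; adjusted p = 0.293 with an estimated correlation). C1orf116 differed by log2 0.32 (95% CI 0.09 to 0.55, limma adjusted p = 0.527) and ZBTB16 by -0.12 (95% CI -0.46 to 0.22). Leaving out any 1 of the 6 arrays gave 3 to 8 genes in place of 17.

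The enzalutamide effect in the presence of each inhibitor used no DMSO array. On top of PF-543, 14 genes were higher and 41 lower. SNAI2 was 5.48-fold lower (log2 -2.45, SE 0.30, limma adjusted p = 0.00264), C1orf116 4.83-fold (log2 -2.27, SE 0.11, adjusted p = 3.78e-07), ZBTB16 4.46-fold (log2 -2.16, SE 0.16, adjusted p = 2.2e-05) and KLF5 3.6-fold (log2 -1.85). DDIT3, the stress factor CHOP, was 3.12-fold higher (log2 1.64, SE 0.19, adjusted p = 0.00167), CHAC1 2.43-fold, DDIT4 2.41-fold, the transcription factor OSR2 1.74-fold and the glycine transporter SLC6A9 1.58-fold. Of 29 androgen-induced genes 9 fell and 0 rose, 14 when adjusted over the list alone (camera adjusted p = 1.03e-28; adjusted p = 0.000107 with an estimated correlation), and of 33 ATF4 genes 6 rose and 0 fell, 18 when adjusted over the list alone (camera adjusted p = 7.22e-25; adjusted p = 0.000107 with an estimated correlation).

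Cholesterol genes shifted down when enzalutamide was added to PF-543, with 1 of 20 lower, HMGCS1 (log2 -0.83, SE 0.13, limma adjusted p = 0.0143), and 8 lower when adjusted over the list alone (median log2 -0.19, camera adjusted p = 1.9e-09; adjusted p = 0.00169 with an estimated correlation). The glucocorticoid receptor list (2 of 10 lower, ZBTB16 and ERRFI1, adjusted p = 0.00283) lost its call with an estimated correlation (adjusted p = 0.112), as did the tRNA synthetases (0 of 16 passing singly, camera adjusted p = 0.00954, then adjusted p = 0.0949). The count of 55 genes became 24 without PF-543 replicate 1, 25 without PF-543 replicate 2, 30 without replicate 2 and 25 without replicate 3 of the combination.

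On top of ABC294640, a comparison of 3 arrays with 1, enzalutamide gave 1 higher and 13 lower genes. C1orf116 was 6.18-fold lower (log2 -2.63, SE 0.15, limma adjusted p = 4.66e-06), ZBTB16 4.38-fold (log2 -2.13, SE 0.22, adjusted p = 0.00119), CDC42EP3 4.06-fold and MAF 3.57-fold, and CHAC1 was the gene that rose (log2 1.46, SE 0.15, adjusted p = 0.00119). Androgen-induced genes fell in 6 of 29 cases, 11 when adjusted over the list alone (camera adjusted p = 1.59e-21; adjusted p = 0.00069 with an estimated correlation). ATF4 targets were higher, with 1 of 33 passing and 4 when adjusted over the list alone (camera adjusted p = 8.68e-09; adjusted p = 0.00655 with an estimated correlation). The glucocorticoid receptor list (1 of 10 lower, adjusted p = 0.0177) and the metallothioneins (0 of 8 passing, adjusted p = 0.00987) lost their calls with an estimated correlation (adjusted p = 0.328 and adjusted p = 0.402). Leaving out any 1 of the 3 combination arrays gave 8 or 9 genes, and the fit on these 4 arrays alone gave 0.

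**Figure D3:**
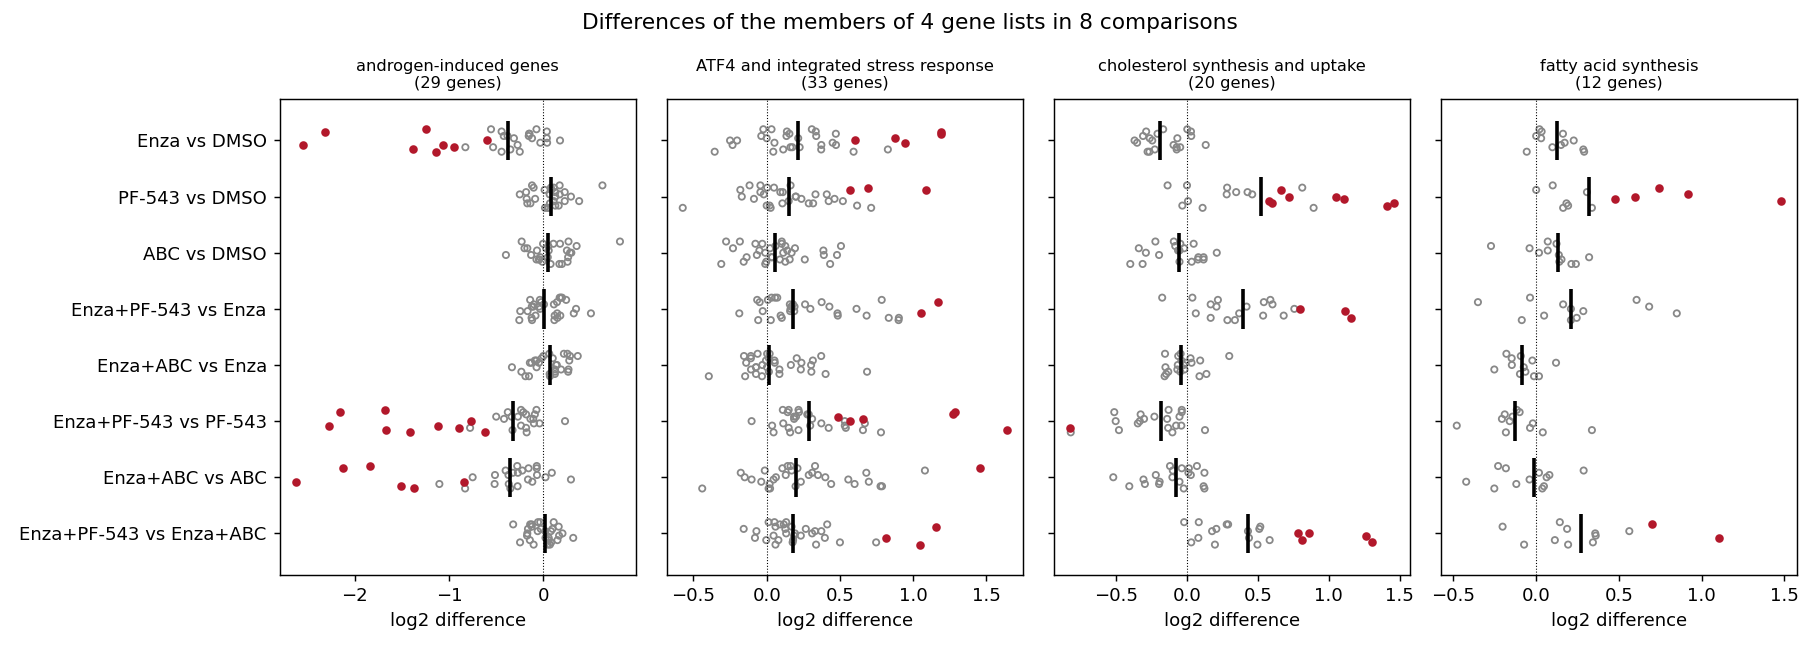
Log2 differences of every measured member of 4 gene lists (29 androgen-induced, 33 ATF4, 20 cholesterol and 12 fatty acid synthesis genes) in 8 comparisons, with filled red points for genes past adjusted p 0.05, open points for the others and a bar at the list median. The androgen-induced medians lie at -0.38, -0.33 and -0.35 in the 3 comparisons that add enzalutamide, and the cholesterol medians at 0.52, 0.39 and 0.43 in the 3 comparisons that add PF-543 or put it in place of ABC294640.

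Against DMSO, the combination of enzalutamide and PF-543 moved the most genes in number, 198 higher and 160 lower. DDIT4 was 5.13-fold higher (log2 2.36, SE 0.13, limma adjusted p = 7.89e-07), CHAC1 3.93-fold (log2 1.97, SE 0.11, adjusted p = 7.89e-07), DDIT3 3.16-fold (log2 1.66, SE 0.19, adjusted p = 0.00114), GDF15 2.81-fold (log2 1.49, SE 0.17) and the cyclin-family gene CCNG2 2.48-fold (log2 1.31, SE 0.11). ZBTB16, C1orf116, CDC42EP3 and KLF5 were among the 5 largest falls, from log2 -2.08 to -1.52. Of the ATF4 list 16 of 33 rose and 0 fell, and 20 rose when adjusted over the list alone (median log2 0.38, camera adjusted p = 8.18e-23; adjusted p = 0.000291 with an estimated correlation). Androgen-induced genes fell in 10 of 29 cases (camera adjusted p = 4.3e-14; adjusted p = 0.00196 with an estimated correlation), while 5 of 20 cholesterol genes rose (camera adjusted p = 7.48e-07; adjusted p = 0.00609 with an estimated correlation) and 5 of 12 fatty acid synthesis genes rose (camera adjusted p = 4.2e-07; adjusted p = 0.0173 with an estimated correlation).

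Another 5 lists passed camera for this combination against DMSO and lost the call with an estimated correlation. They were the glucocorticoid receptor targets, with TSC22D3 higher and ZBTB16 and ERRFI1 lower (adjusted p = 0.0265, then adjusted p = 0.225), and the tRNA synthetases, with SARS1 and NARS1 of 16 higher (adjusted p = 0.0265, then adjusted p = 0.122). The others were endoplasmic reticulum chaperones, with XBP1, EDEM1 and HERPUD1 of 23 higher (adjusted p = 0.0261, then adjusted p = 0.0723), NRF2 targets, with SLC7A11 of 23 higher (adjusted p = 0.00164, then adjusted p = 0.0723), and the metallothioneins (adjusted p = 0.00907, then adjusted p = 0.26). The count of 358 genes was 201 without DMSO replicate 1, 139 without DMSO replicate 2, and 130, 115 and 131 without replicate 1, 2 and 3 of the combination.

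The combination of enzalutamide and ABC294640 gave 60 higher and 64 lower genes against DMSO. C1orf116 was 5.14-fold lower (log2 -2.36, SE 0.11, limma adjusted p = 2.33e-07), and ZBTB16 (log2 -1.95), KLF5 (-1.94) and CDC42EP3 (-1.81) were also among the 5 largest falls. CHAC1 was 2.95-fold higher (log2 1.56, SE 0.11, adjusted p = 1.31e-05), DDIT4 2.31-fold (log2 1.21, SE 0.13, adjusted p = 0.000794), the junction protein PLEKHA7 2.03-fold, CEP85L 1.93-fold and SESN2 1.93-fold. Androgen-induced genes fell in 9 of 29 cases and ATF4 targets rose in 8 of 33 (camera adjusted p = 3.57e-15 and 8.95e-13; adjusted p = 0.0016 for both with an estimated correlation). Cholesterol genes shifted down, with 1 of 20 lower, MSMO1 (log2 -0.50, SE 0.09, adjusted p = 0.0315; camera adjusted p = 0.000908, and adjusted p = 0.0395 with an estimated correlation). MYC and ribosome biogenesis genes shifted up, with MYC of 18 passing (camera adjusted p = 0.000113; adjusted p = 0.0395 with an estimated correlation). The glucocorticoid receptor list (2 of 10 lower, adjusted p = 0.00408) and the metallothioneins (0 of 8 passing, adjusted p = 0.000741) lost their calls with an estimated correlation (adjusted p = 0.148 and adjusted p = 0.251). Leaving out any 1 of the 6 arrays gave 49 to 77 genes in place of 124.

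Whether the drugs acted together by more or less than the sum of their log2 effects was tested with an interaction term. The term uses the DMSO arrays for both inhibitors, so a shift of those arrays would enter each value. No gene passed for PF-543 (limma, smallest adjusted p = 0.21; 1428 genes with an unadjusted p under 0.05 and 884 by chance; 12 genes with a robust prior trend) or for ABC294640 (smallest adjusted p = 0.21; 1459 genes; 1 gene with a robust prior trend). For DDIT4 the interaction with PF-543 was log2 0.08 (95% CI -0.34 to 0.49), for CHAC1 0.10 (95% CI -0.25 to 0.44), for INSIG1 -0.25 (95% CI -0.63 to 0.12), for DDIT3 0.81 (95% CI 0.19 to 1.44, adjusted p = 0.525) and for HMGCS1 -0.78 (95% CI -1.19 to -0.37, adjusted p = 0.416). The smallest p belonged to GDNF-AS1 (log2 1.14), GPR151 (1.24) and HPCAL1 (-1.04) for PF-543, and to ZBTB14 (1.05), TLK1 (-1.29) and INSL5 (-1.30) for ABC294640. By camera 3 lists had a lower interaction term with PF-543, fatty acid synthesis (adjusted p = 0.00539), MYC and ribosome biogenesis (adjusted p = 0.00725) and metallothioneins (adjusted p = 0.0147), with no member passing singly. All 3 lost the call with an estimated correlation (adjusted p = 0.278, adjusted p = 0.278 and adjusted p = 0.527) and with fry. For ABC294640 no list passed. Without enzalutamide replicate 2 the 3 lists for PF-543 became 1, and without enzalutamide replicate 1 the 0 lists for ABC294640 became 3.

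Across 17687 genes, the PF-543 effect against DMSO and its effect on top of enzalutamide, which share no array, correlated at Pearson r = 0.17 and Spearman rho = 0.16. The corresponding ABC294640 effects correlated at r = 0.01 and rho = 0.01, and at r = -0.034 without enzalutamide replicate 2 and -0.02 without replicate 2 of the combination with ABC294640. Enzalutamide against DMSO correlated with enzalutamide on top of PF-543 at r = 0.19 and rho = 0.13, and with enzalutamide on top of ABC294640 at r = 0.07 and rho = 0.02. Crossed inhibitors gave r = 0.09 for PF-543 against DMSO with ABC294640 on top of enzalutamide, and 0.10 for the reverse pair. Genes are not independent replicates, so no p is attached to these 6 values. The calls compared next share each gene's pooled spread, so the numbers given for independent lists are not an exact baseline. Of the 33 genes that fell with enzalutamide against DMSO, 21 also fell on top of PF-543, where independent lists would share 0.076, and 32 had the same sign. On top of ABC294640, 12 of the 33 fell (0.024 for independent lists). Of the 22 genes that rose with enzalutamide, 5 also rose on top of PF-543 (0.017 for independent lists) and 1 on top of ABC294640 (0.0012). Of the 64 rises with PF-543 against DMSO 4 were shared with PF-543 on top of enzalutamide (0.018 for independent lists), and of the 36 falls 0 were, where limma called 0 falls on top of enzalutamide and 4 of the 36 had an unadjusted p under 0.05 with the same sign.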

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

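The test of signal range and the comparisons without DMSO arrays were chosen after the DMSO arrays were seen to stand apart. Both of the following kinds of result were picked out for a closer look: gene lists whose enzalutamide effect differed with and without PF-543, and probe sets without a gene name that passed the test.

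By camera the enzalutamide effect was lower in the presence of PF-543 than in its absence for fatty acid synthesis genes (mean log2 difference -0.222), MYC and ribosome biogenesis genes (-0.192) and metallothioneins (-0.251). None of the 3 passed with an estimated correlation (adjusted p = 0.278, 0.278 and 0.527) or with fry (adjusted p = 0.0597, 0.0597 and 0.18). The effect without PF-543 rests on the DMSO arrays. Unnamed probe sets past the threshold numbered 11 for enzalutamide, 19 for PF-543, 54 for enzalutamide with PF-543 and 27 for enzalutamide with ABC294640, each against DMSO. They numbered 3 for the PF-543 combination against enzalutamide, 3 for it against PF-543, 1 for the ABC294640 combination against ABC294640 and 5 between the combinations.

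The separation of the DMSO arrays from all treated arrays bears on every comparison with DMSO. At adjusted p under 0.05, 359 genes set DMSO apart from the mean of the other groups, against 5 to 55 for each treated group. A narrower range of signal on the DMSO arrays as the whole cause is argued against by cyclic loess, which removes trends with signal and left 275 such genes, with at most 56 for any treated group. A separate processing day stays open, since 0 label fields give a date or batch, and it cannot be told apart from the vehicle group. A response shared by all drug treatments was not tested and also stays open. The vehicle dose is recorded for the DMSO arrays only, so whether it was matched in the treated wells is not known here.

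How much of each drug's response could come from the DMSO arrays alone was tested on arrays outside the call. The intervals below resample genes with the arrays held fixed. They do not measure the spread between arrays, and genes are not independent replicates. The falls with enzalutamide kept 72.2% of their median size on top of PF-543 (95% bootstrap interval over genes 59.9 to 96.6). Of these 33 genes, 32 had the same sign there and 21 passed again, which argues against a DMSO shift as their main source. The falls with PF-543 kept 6.8% (-4.7 to 16.4) on top of enzalutamide, consistent with a shift of the DMSO arrays, while falls that occur only without enzalutamide stay open too. The rises with PF-543 kept 47.9% (30.2 to 57.4) and the rises with enzalutamide 52.5% (25.6 to 69.8), and both intervals include the 50% set as the dividing value, so a DMSO shift stays open for part of these genes. The cholesterol list had a mean of log2 0.44 with PF-543 on top of enzalutamide (camera adjusted p = 5.92e-18), against 0.55 with DMSO as the reference. For that list, which was fixed in advance, the values argue against a DMSO shift as the main source of its rise. The fatty acid synthesis list kept less, with a mean of 0.24 against 0.46. Genes called against DMSO were selected for size there, so some loss of size would be seen without any shift.

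Other splits of the same 6 arrays were counted for the comparisons of 3 with 3. The real split was in each case the 1 of 10 with the most genes, and 10 splits are too few for a share under 0.05. Real and highest other counts were 100 and 0 for PF-543 against DMSO, 358 and 0 for enzalutamide with PF-543 against DMSO, 124 and 0 for enzalutamide with ABC294640 against DMSO, 55 and 0 for the PF-543 combination against PF-543, and 17 and 1 between the combinations.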

How the results depend on the processing

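Cyclic loess and the contrasts without DMSO arrays were chosen after seeing the data. Unless another cause is given, the cause of a change was not tested. Same-numbered arrays did not deviate together (26 pairs, r from -0.037 to 0.072, 0 over 0.1), so no effect shared by replicate number was visible over all genes. Whether same-numbered samples were handled together is not given in the labels. With the replicate block the count was 46 for PF-543, 236 for enzalutamide with PF-543 and 74 for enzalutamide with ABC294640 against DMSO, 3 for the PF-543 combination against enzalutamide and 4 between the combinations. In the order enzalutamide, PF-543, ABC294640, enzalutamide with PF-543 and enzalutamide with ABC294640, each against DMSO, a robust trended prior gave 266, 547, 8, 1121 and 599 genes; for the other contrasts it gave 47 for the PF-543 and 1 for the ABC294640 combination against enzalutamide, 147 against PF-543, 38 against ABC294640, 28 between combinations, and 12 and 1 for the interactions with PF-543 and ABC294640. Fitting only a contrast's arrays, which leaves fewer degrees of freedom, gave 3 for enzalutamide, 9 for PF-543, 31 and 23 for the PF-543 and ABC294640 combinations against DMSO, 0 and 17 for the PF-543 combination against enzalutamide and PF-543, 0 against ABC294640 and 4 between combinations. Without the dimmest 25% of genes the counts were 177, 545 and 210 for PF-543 and both combinations against DMSO and 8 for the PF-543 combination against enzalutamide, which was also 8 with all probe sets and 8 with array weights. A minimum of 2-fold left 23, 15, 34 and 18 genes for enzalutamide, PF-543 and both combinations against DMSO, 16 for the PF-543 combination against PF-543 and 5 between combinations; with unadjusted p these were 33, 19, 37, 19, 17 and 5, and 39 for ABC294640, 4 for its combination against enzalutamide, 46 against ABC294640, and 35 and 165 for the interactions with PF-543 and ABC294640. Leaving out 1 array gave 12 to 58 genes for enzalutamide, 25 to 59 for PF-543, 0 to 1 for ABC294640, 115 to 260 and 49 to 77 for the PF-543 and ABC294640 combinations against DMSO, 0 to 3 for the PF-543 combination against enzalutamide, 24 to 39 against PF-543, 8 to 9 against ABC294640 and 3 to 8 between combinations. Lists called ranged from 0 to 1 for the ABC294640 and 3 to 7 for the PF-543 combination against enzalutamide, and 1 to 3 and 0 to 3 for the interactions with PF-543 and ABC294640. An estimated correlation left 3 lists for enzalutamide, 3 for PF-543, 4 for the PF-543 combination against DMSO, 2 and 3 against enzalutamide and PF-543, 0 and 2 for the ABC294640 combination against enzalutamide and ABC294640, and 0 for the interaction with PF-543. Fry gave 15 for the PF-543 combination against DMSO, 3 against enzalutamide, 0 and 2 for the ABC294640 combination against enzalutamide and ABC294640, and 0 for the interaction with PF-543; the robust prior gave 3 for ABC294640, 9 for the PF-543 combination against enzalutamide, and 6 and 4 for the interactions, and fitting only a contrast's arrays gave 0 for the ABC294640 combination against enzalutamide. Without DMSO arrays, PF-543 had 5 genes in place of 100 and ABC294640 had 1 list. ANKS1B (log2 0.142), ZFTA (0.237), CYBB (0.238), TLK1 (-0.172) and the heat shock (-0.005), fatty acid (-0.082) and ribosomal protein (-0.004) lists under enzalutamide changed sign. The values under enzalutamide weigh the single ABC294640 array like the PF-543 arrays. With PF-543, adding enzalutamide took TLK1 from 10.84 to 10.9 and CYBB from 5.06 to 5.05, so their changes of sign came from the ABC294640 array. Correlations over called genes only were 0.626 for PF-543 with its effect on enzalutamide, 0.851 and 0.816 for enzalutamide with its effect on PF-543 and ABC294640, 0.197 for PF-543 with ABC294640 on enzalutamide and -0.518 for the reverse. Genes picked for size raise such values. The value of -0.518 covers only the 5 genes called for PF-543 on top of enzalutamide, with a 1-array ABC294640 effect on the other side. No direction of the inhibitors' effects can be read from it. Without the dimmest 25% the enzalutamide values were 0.252 and 0.116. Spearman's rho, over all genes tested, was 0.127 and 0.022. The near-zero ABC294640 value was -0.006 with quantile normalization, -0.005 with cyclic loess and -0.034 to 0.049 with 1 array left out. Among the lists called and the called genes picked by the rule, some of them not reported here, 123 gene and 47 list calls held under cyclic loess, and 2 and 4 did not. With the replicate block 91 gene calls held and 27 did not, and with only a contrast's arrays 51 held and 74 did not. Without DMSO arrays 17 gene calls held, 25 were lost and 4 changed sign. Signal over background was not measured.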

Other observations

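The FOXO target list was written, and its test chosen, after CCNG2, TSC22D3 and SESN3 were seen to be higher with PF-543.

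Genes of sphingolipid metabolism and sphingosine-1-phosphate signalling, the pathway both inhibitors act on, did not pass camera in any of the 12 contrasts (40 measured, smallest adjusted p = 0.401, medians from log2 -0.045 to 0.05). The same held for androgen-repressed genes (smallest adjusted p = 0.222), estrogen receptor targets (0.204), LXR targets (0.174), lysosome and autophagy genes (0.0875), p53 targets (0.065), G1/S genes (0.0757), G2/M genes (0.222), ERK output (0.24), hypoxia and glycolysis genes (0.554), NF-kB targets (0.184), interferon-stimulated genes (0.366), aryl hydrocarbon receptor genes (0.446), the BCL2 family (0.687) and neuroendocrine markers (0.483). Markers of other cell types did not pass either, with smallest adjusted p of 0.222 for fibroblast, 0.432 for leukocyte and 0.222 for basal epithelial genes. With fry, which does not compare a list with other genes, 6 of these lists passed. They were ERK output (adjusted p = 0.0158, down) and NF-kB targets (0.0261, down) with enzalutamide, and the same lists (0.0364 and 0.0121, down), G1/S genes (0.0147, down), LXR targets (0.0306, up) and fibroblast markers (0.0428, down) with enzalutamide plus PF-543, all against DMSO. LXR targets also passed fry with enzalutamide plus ABC294640 against DMSO (0.019, up), and androgen-repressed genes when enzalutamide was added to PF-543 (0.0364, down). Single members passed in some of these lists: against DMSO, the p53 targets CDKN1A and MDM2 were higher and TP53I3 lower with PF-543, and NFKBIA was lower with both combinations. In comparisons of treated groups only, NFKBIA was lower with the PF-543 combination than with PF-543 alone. CDKN1A was higher with the PF-543 combination than with the ABC294640 combination. These genes were chosen after their values were seen.

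A hypothesis was that PF-543 raises targets of FOXO transcription factors more widely. CCNG2, TSC22D3 and SESN3 were at log2 0.77, 0.79 and 0.52 with PF-543 against DMSO, and at 0.73, 0.84 and 0.36 between the combinations. Without these 3, the 16 other measured targets were shifted up by PF-543 against DMSO (14 of 16 positive, median log2 0.102, camera p = 0.0303 with an estimated correlation) but did not pass between the combinations, which share no array with it (12 of 16 positive, median 0.035, p = 0.534). On top of enzalutamide alone the p was 0.0585, with 10 of 16 positive. None of the 16 passed singly in these comparisons, and the p-values are unadjusted. The bootstrap interval of the median was 0.06 to 0.297 against DMSO and 0.01 to 0.077 between the combinations. The rule set asked for both intervals under 0.1 to argue against a wider rise, and only the second met it. A wider rise therefore stays open. The DMSO arrays enter only the contrast that passed.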
